A study of Homo sapiens with 8 samples.

How the data were processed

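Total RNA of HTR8 cells was taken up in Trizol and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The protocol names a kit for small RNA libraries. Most genes of the deposited table that could be matched and were tested are protein coding (87.5%), and none of the 1877 listed microRNA genes was among the tested genes, so the label and the table differ on the kind of RNA measured. The genome build is GRCh38, per the submitters' processing notes. The aligner, the counting step, the scaling and the test behind the deposited values are not given in the sources used here. The labels place 4 samples in the exosome co-culture group and 4 in the untreated group, and they name no vehicle or exosomes of another source as a control.

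The file holds a table of the authors' own comparison. Per the file headers, it gives the fold (a ratio of exosome co-culture over untreated), its log2 value, and a p-value and adjusted p-value, all made by the authors. The deposited log2 values equal the log2 of the fold for every gene within 2.04e-11. The deposited adjusted p-value equals the Benjamini-Hochberg value over the 13840 genes with an adjusted p below 1, within 1.81e-12. It is exactly 1 for 15608 other genes with a fold other than 1, and 32093 genes have a fold of exactly 1. The authors' mark of significance matches an adjusted p under 0.05 with an absolute log2 fold of at least 1 for all 61541 genes.

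A count model with groups as the only factor, and a set test with the same design, had been planned before the data were examined. The table holds no values per sample, so neither could be run, and the authors' p-values took their place. Tests of library composition, leaving out samples, blocking on replicate number and regrouping of samples could not be run for the same reason. The depth of each sample is unknown, and the authors gave no interval or standard error. A standard error was implied per gene from the log2 fold and the two-sided p, taken as that of a normal statistic.

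Gene lists were set before the table was seen: 39 lists on metabolism, stress, growth, trophoblast identity and other cell types, with 981 distinct genes in the table and 2 symbols without a row. For each list with at least 5 tested members (36 lists), cameraPR of limma 3.58.1 (R 4.3.3) was run on a signed z value made from the authors' two-sided p, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. A correlation estimated from samples could not be had, so correlations of 0.05 and 0.1 were added. A further 5 lists (LXR targets, interferon signalling, FOXO targets, SRF targets and abundant placental transcripts) were written after the table was seen and adjusted among themselves. These were run at a correlation of 0.01 only. The values of the interferon signalling genes had not been looked at when that list was written, while 1 LXR target, SMPDL3A, and members of the FOXO and SRF lists had been. With z shuffled over the 13840 genes in 100 draws, 0.194% of lists were called. Shuffling removes the correlation between genes of a list, so this rate does not bear on false calls that such correlation makes. Lists shifted by 1 in z were recovered in 17% of cases, and those shifted by 2 in 90.6%.

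GO biological process terms and KEGG maps were taken from the columns of the deposited table, with 10 to 500 tested members, and tested by one-sided Fisher's exact test against tested genes that carry any term of the kind. Shuffled genes gave 0 calls in 20 draws for each kind. These shuffles also removed correlation between genes, for which Fisher's exact test makes no allowance. Gene coordinates, biotypes, overlaps and transcript GC came from GENCODE 29 on GRCh38, matched by gene ID for 98.8% of tested genes. A trend of the second degree in log2 transcript length and GC, fitted to values clipped at the 1st and 99th percentiles, took up 4.04% of the variance of log2 fold changes. A trend of the fourth degree in GC, chosen after the curve over GC was seen, took up 4.64%. Sites of 20 microRNA families, 7 bases long, were counted in the longest annotated 3 prime UTR of 11530 protein-coding genes. The 19 families with sites in at least 100 genes were tested with UTR length and GC as covariates. Simulated data were made in 5 runs per effect, each with log2 folds shuffled over genes and 1 randomly drawn family lowered. That family was called lower at an adjusted p under 0.05 in 3 runs at an effect of -0.05 and in 5 at -0.1. With no effect, 1 of 100 families was called lower.

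Named genes followed a rule: the 10 largest log2 fold changes in each direction among protein-coding genes past the threshold, and the 4 members with the smallest p of each list described. The parts of the rule on a mean of 50 counts and on separation of all samples could not be applied. A gene on chromosome Y or XIST was never named. Genes outside the rule (DHCR24, PMVK, SREBF1, PLIN2, BST2, PEG10, GTPBP4, TCOF1, NPR1, the proteasome genes and the genes in the closing section) were chosen after their values were seen. H2AC18 was not eligible because its ID had no match in the annotation. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.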

Results

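RNA of the human trophoblast cell line HTR8, an immortalised line derived from first-trimester placental villi, was sequenced after co-culture with exosomes and without treatment. Exosomes are small vesicles that cells release and that carry RNA, protein and lipid. The labels give 8 samples in 2 groups, 4 with exosome co-culture and 4 untreated. The series concerns exosomes from placentas of pregnancies with gestational diabetes, microRNA transfer, and the pathways that differ between normal and co-cultured cells. The labels do not say whether the exosomes given to these cells came from normal or gestational diabetes placentas. The values analysed were the authors' own comparison of the groups, a fold change, p-value and adjusted p-value per gene. Values of single samples were not analysed here, so the depth of each sample and the spread between replicates are unknown. Standard errors can only be implied from the log2 fold and p. The labels do not say whether the 4 samples of a group came from separate cultures, so the p-values may measure technical spread only.

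Cells co-cultured with exosomes had lower levels of most transcripts for cholesterol synthesis, and many transcripts for fatty acid synthesis, amino acid stress and interferon response were lower too. Many transcripts for glycolysis, chaperones and the proteasome were higher. Of 61541 genes listed in the authors' deposited table, 13840 had an adjusted p-value below 1, and these were taken as the genes tested. At an adjusted p under 0.05, 1082 genes were higher and 951 were lower in the authors' deposited table, and 3759 had an unadjusted p under 0.05. Most changes were small: the median log2 fold change was 0.32 among the higher genes and -0.43 among the lower genes of the authors' deposited table. Only 28 higher and 89 lower genes in the authors' deposited table also changed by at least 1 on the log2 scale, and these 117 carry the authors' own mark of significance. The median log2 fold change of tested genes varied with the GC content of the transcript in the authors' deposited table. It was -0.10 in the lowest of 20 GC bins, 0.08 in the bin from 52.8% to 54.5% GC and -0.15 in the highest bin. The median standard error implied by the log2 fold and p was 0.106 in the lowest bin and 0.215 in the highest. The untreated cells were the only control, and no cells given other exosomes were part of the comparison.

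**Figure D1:**
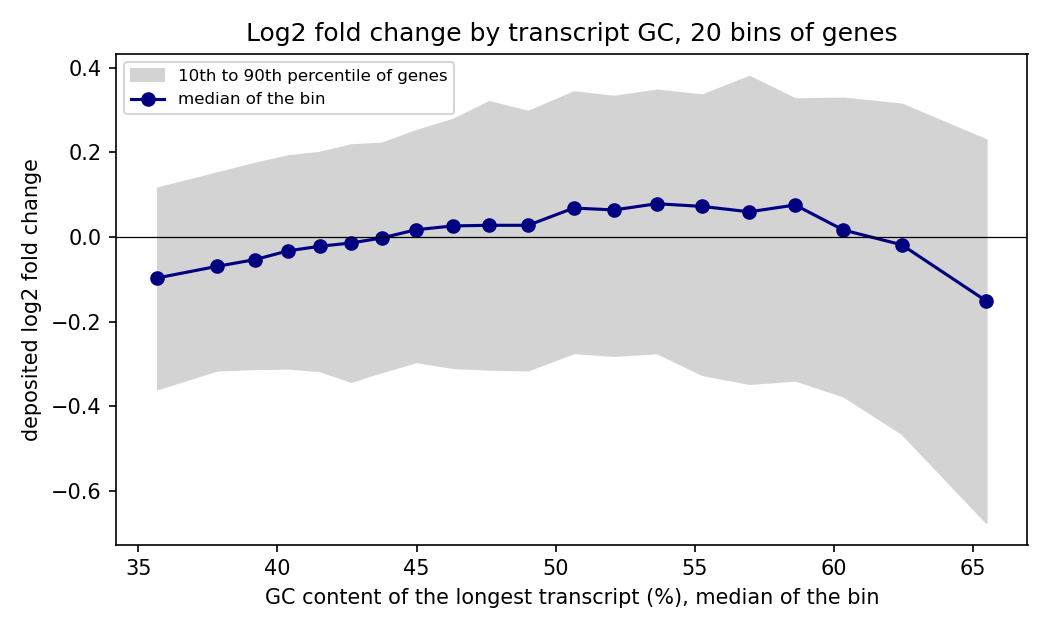
Deposited log2 fold change (exosome co-culture over untreated, vertical axis) of tested genes in 20 bins of transcript GC content (percent, horizontal axis), with the median of each bin as a line and a grey band for the spread of genes within each bin (bounds in the legend). The median runs from -0.10 in the lowest bin through 0.08 to -0.15 in the highest bin of the authors' deposited table.

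The gene with the largest increase among protein-coding genes past the threshold was PPFIA4, a liprin scaffold protein (ENSG00000143847, chromosome 1, 203026498 to 203078740, GRCh38), with a log2 fold change of 3.72 and an adjusted p of 7.88e-08 in the authors' deposited table. CPA4, a secreted carboxypeptidase (ENSG00000128510, chromosome 7, 130293134 to 130324180), had a log2 fold change of 2.31 in the authors' deposited table, with an adjusted p of 2.5e-38. The macrophage and lysosome marker CD68 was 3.99-fold higher in the authors' deposited table (adjusted p = 4.37e-06), and the deiodinase DIO2, which activates thyroid hormone, 3.13-fold (adjusted p = 0.00147). IGFBP3, which binds insulin-like growth factors, was higher by 1.51 in the authors' deposited table (adjusted p = 7.39e-25). The other genes of this group in the authors' deposited table were NPY4R2 at 1.98, LDLRAD2 at 1.63, C11orf86 at 1.51, ANKRD2 at 1.39 and the endothelin gene EDN2 at 1.39. CD68 overlaps a noncoding gene on its own strand, LDLRAD2 overlaps HSPG2 on the other strand and NPY4R2 has a near-identical copy, so reads of these genes may be shared. The planned bound of a mean of 50 counts could not be applied. Genes named by the largest change, in either direction, may therefore rest on few reads.

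The largest decrease was that of CXCL11, an interferon-induced chemokine (ENSG00000169248, chromosome 4, 76033682 to 76041415), with a log2 fold change of -2.38 and an adjusted p of 4.06e-06 in the authors' deposited table. PRUNE2 stood at -2.09 and the lysosomal protease CTSS at -1.96 in the authors' deposited table, with adjusted p-values of 9e-31 and 3.62e-05. ACSS2, which makes acetyl-CoA from acetate (ENSG00000131069, chromosome 20, 34872146 to 34927962), was 3.51-fold lower and had the smallest adjusted p of the authors' deposited table, 5.53e-107. Also lower in the authors' deposited table were RSAD2, an antiviral protein, at -1.79, KLHL38 at -1.70 and LIPE, hormone-sensitive lipase, at -1.69. The remaining genes were the sterol enzymes TM7SF2 at -1.78, MVD at -1.69 and HMGCS1 at -1.62 in the authors' deposited table. CXCL11 lies opposite ART3, RSAD2 opposite CMPK2 and ACSS2 opposite GGT7, and TM7SF2 overlaps VPS51 on its own strand. Of all genes named by the largest change in either direction, 12 overlap an annotated gene, not all of them given here. The transcripts of TM7SF2 and MVD had 64.2% and 63.7% GC, at the upper end where the median of all genes was below 0. The labels do not say whether reads were counted by strand.

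Genes of cholesterol synthesis and uptake were lower together: 22 of 24 tested members passed the gene test as lower and none as higher, with a median log2 fold change of -0.94 in the authors' deposited table. The mevalonate enzymes HMGCS1 (chromosome 5, 43289395 to 43313512) and IDI1 stood at -1.62 and -1.29 in the authors' deposited table, the cyclase LSS at -1.21 and INSIG1, which senses sterols, at -1.41. The exceptions were DHCR24 at -0.14 and PMVK at -0.27 in the authors' deposited table, which did not pass. The list held 23 lower members when adjusted over the list alone. The competitive set test gave an adjusted p of 7.46e-107 at a preset correlation between genes of 0.01 and 1.77e-40 at 0.1. Transcript GC had a median of 50.3% in the list.

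Of 21 tested genes of fatty acid synthesis, 12 fell and 1 rose, and the median log2 fold change was -0.38 in the authors' deposited table. ACSS2 was followed by the phosphatidate phosphatase LPIN1 at -1.11, the acyl-CoA synthetase ACSL1 at -1.13 and the desaturase SCD at -1.36 in the authors' deposited table. SREBF1, which encodes a transcription factor of lipid synthesis, stood at -0.89 in the authors' deposited table (adjusted p = 5.36e-07). The lipid droplet coat gene PLIN2 was the member that rose, with a log2 fold change of 0.53 in the authors' deposited table. There were 12 lower and 3 higher members adjusted over the list alone. The set test gave an adjusted p of 1.7e-23, and 1.39e-09 at a correlation of 0.1.

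**Figure D2:**
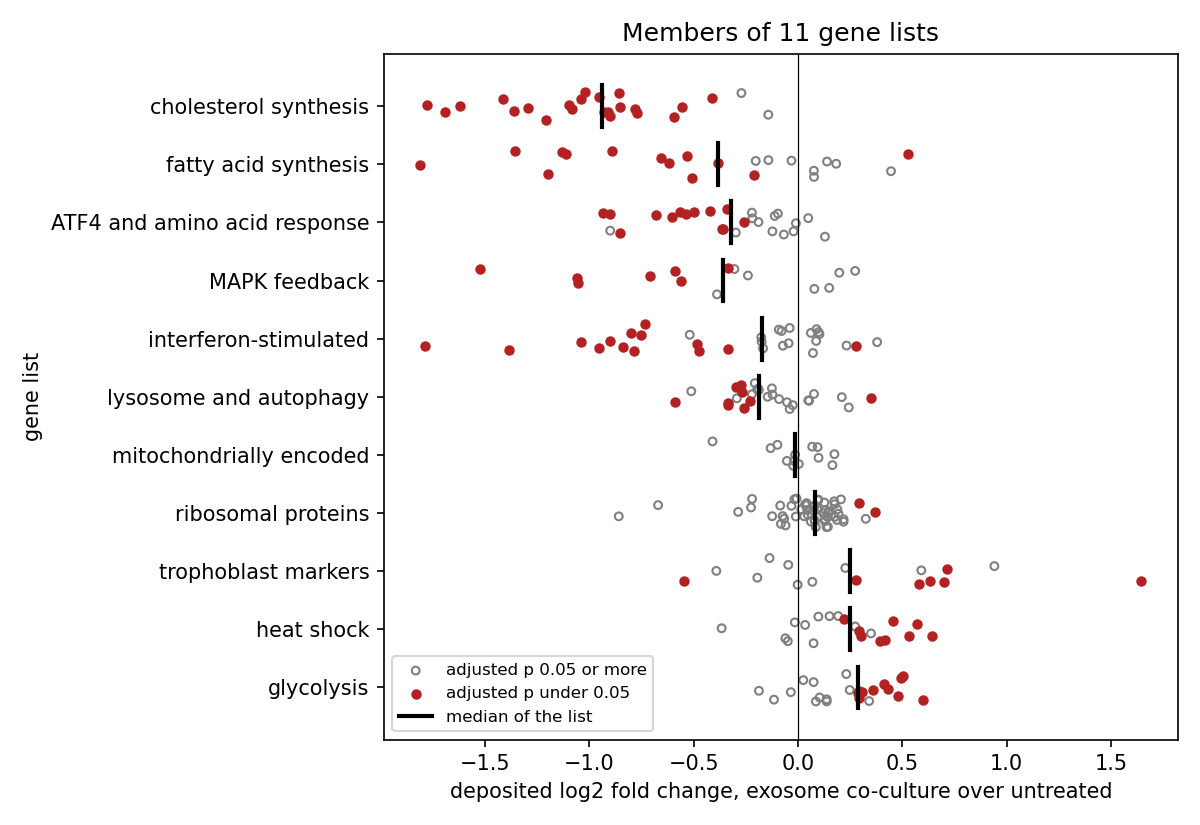
Deposited log2 fold change (exosome co-culture over untreated, horizontal axis) of the tested members of 11 gene lists (vertical axis), as points, with the median of each list as a black line. Filled points passed an adjusted p of 0.05 in the authors' deposited table; the medians run from -0.94 for cholesterol synthesis to 0.29 for glycolysis.

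Targets of ATF4 and genes of the amino acid response were lower in 13 of 26 tested members and higher in none, with a median of -0.32 in the authors' deposited table. The pseudokinase TRIB3 stood at -0.85, the serine synthesis enzyme PHGDH at -0.54, the folate enzyme ALDH1L2 at -0.57 and the cystine transporter SLC7A11 at -0.36 in the authors' deposited table. With the length and GC trend removed SLC7A11 was at -0.21 and still past the threshold. With p-values adjusted over the list alone, 14 were lower. The set test gave an adjusted p of 3.29e-09, and 0.00162 at a correlation of 0.1. Feedback genes of MAPK signalling were lower in 7 of 14 tested members and higher in none, and the authors' deposited table gave ETV5 at -1.53, SPRY1 at -1.06, PHLDA1 at -0.71 and DUSP4 at -0.56. Adjusted over the list alone, 9 were lower and 1 was higher. The adjusted p of this set was 1.74e-04, and 0.0187 at a correlation of 0.1.

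Interferon-stimulated genes fell in 13 of 31 tested members and rose in 1, with a median log2 fold change of -0.17 in the authors' deposited table. IFIT3, IFIT2, OASL and HERC5, antiviral effectors, stood at -0.95, -0.80, -0.90 and -0.47 in the authors' deposited table. BST2, which tethers virions to the cell surface, was the member that rose, by 0.28 in the authors' deposited table. Adjusted over the list alone the counts were also 13 and 1. The adjusted p of the set was 3.32e-08, and 0.00458 at a correlation of 0.1.

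Glycolysis genes rose in 11 of 23 tested members and fell in none, with a median of 0.29 in the authors' deposited table. LDHA, which makes lactate, stood at 0.60, the hexokinase HK1 at 0.41, PGAM1 at 0.51 and the pyruvate kinase PKM at 0.50 in the authors' deposited table. Adjusted over the list alone, 14 were higher. The set test gave an adjusted p of 2.08e-07, and 0.00458 at a correlation of 0.1. Transcript GC had a median of 53.3% in this list, within the range where the median of all genes lay above 0. Other metabolic lists did not pass. The tricarboxylic acid cycle had 5 of 27 members higher and 2 lower (adjusted p = 0.146), nuclear respiratory chain genes 3 of 45 higher (adjusted p = 0.214) and fatty acid oxidation 4 of 22 higher and 2 lower (adjusted p = 0.391). None of the 13 mitochondrially encoded genes passed the authors' test or had an unadjusted p under 0.05, and the set adjusted p was 0.851. The enzymes IDH1, OGDH and SDHB stood at -0.37, 0.33 and 0.33, and ACADVL and PDK4 at 0.36 and -0.55 in the authors' deposited table.

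Heat shock and chaperone genes rose in 9 of 20 tested members and fell in none, with a median of 0.25 in the authors' deposited table. The chaperones HSP90AA1 and HSP90AB1 stood at 0.45 and 0.57, the mitochondrial chaperonin HSPD1 at 0.42 and the cochaperone STIP1 at 0.53 in the authors' deposited table. Adjusted over the list alone, 13 were higher. The set test gave an adjusted p of 3.7e-08, and 0.00162 at a correlation of 0.1. 

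Genes of the proteasome, which degrades tagged proteins, were higher as a group. Among KEGG maps in the authors' deposited table, the proteasome had the smallest adjusted p, with 25 of 43 tested members higher where 4.41 were expected (one-sided Fisher's exact test, adjusted p = 6.74e-12). PSMD3, PSMD4, PSMC3 and PSMD2 stood at 0.46, 0.41, 0.48 and 0.46 in the authors' deposited table. Ribosome biogenesis had 19 of 68 members higher where 6.97 were expected (adjusted p = 0.00177), and the spliceosome 26 of 126 where 12.9 were expected (adjusted p = 0.015). Of the lower KEGG maps, steroid biosynthesis had 11 of 18 members lower where 1.41 were expected (adjusted p = 3.48e-06) and the lysosome 18 of 107 where 8.37 were expected (adjusted p = 0.0437). The lysosome call was lost with the length and GC trend removed (adjusted p = 0.127, or 0.079 with the fourth degree in GC), with 16 or 17 members past the threshold and a median of -0.02 or -0.03 beside -0.03 before. In all, 13 of 309 maps passed as higher and 7 as lower, and 7 of the 13 held at least 10 proteasome genes among the members that passed. Ribosome biogenesis members GTPBP4 and TCOF1 stood at 0.38 and 0.35, and lipolysis members LIPE and NPR1 at -1.69 and -0.62 in the authors' deposited table.

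GO terms were tested in the same way. Messenger RNA splicing had 55 of 246 members higher where 22.2 were expected (adjusted p = 3.33e-08) and ribosomal RNA processing 36 of 144 (adjusted p = 1.55e-06). Canonical glycolysis had 8 of 20 members higher (adjusted p = 0.015) and actin filament organization 16 of 67 (adjusted p = 0.0167). With the length and GC trend removed, the actin term was no longer called (adjusted p = 0.0968), while with the fourth degree in GC it was (adjusted p = 0.0398). The median log2 fold change of its members was 0.08 before, 0.15 with the trend removed and 0.10 with the fourth degree, so fewer members passed (13 in place of 16) while the median did not shrink. Cholesterol biosynthesis had 19 of 30 members lower where 2.16 were expected (adjusted p = 4.32e-12). Positive regulation of glucose import had 7 of 16 members lower (adjusted p = 0.00508), a call lost with the fourth-degree trend removed (5 members, adjusted p = 0.127), where the median went from -0.24 to -0.15. Amino acid transport had 7 of 22 members lower (adjusted p = 0.0339). Of 1629 terms, 51 passed as higher and 18 as lower, and 27 of the 51 held at least 10 proteasome genes among the members that passed.

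Trophoblast markers rose in 6 of 16 tested members and fell in 1, with a median of 0.25 in the authors' deposited table. The list had 26 members with a row, 5 of them with a fold of exactly 1. The keratin KRT7, the integrin ITGA5, the protease inhibitor SERPINE1 and the transcription factor GATA2 stood at 0.63, 0.70, 0.58 and 0.72 in the authors' deposited table. KRT7 and ITGA5 also belong to the epithelial and mesenchymal list and SERPINE1 to the TGF-beta targets, so these list calls are not independent. PEG10, a retrotransposon-derived placental gene, was the member that fell, with a log2 fold change of -0.55 in the authors' deposited table. Adjusted over the list alone, 8 were higher and 2 lower. The set adjusted p was 0.00367, and the call was lost at a correlation of 0.1, where the adjusted p was 0.11, and with ranks in place of z. Markers of the syncytiotrophoblast, the hormone-making outer layer of the placenta, rose in 4 of 11 tested members and fell in 1, and the set did not pass (adjusted p = 0.0573). ALPP, PSG4 and PSG5 stood at 0.46, 0.37 and 0.78 and the hormone subunit CGA at -0.47 in the authors' deposited table. PSG4 and PSG5 belong to a family of near-identical genes, so their reads may be split. Of markers of other cell types, no erythroid gene was tested, 1 leukocyte gene was tested and rose (CD68) and none of 4 tested endothelial genes passed the authors' test, with 1 at an unadjusted p under 0.05. That gene was VWF, at 0.90 in the authors' deposited table.

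Lysosome and autophagy genes fell in 8 of 28 tested members and rose in 1, among them MCOLN1 at -0.59, NPC1 at -0.33, NPC2 at -0.34 and CTSL at -0.30 in the authors' deposited table. The set adjusted p was 0.00211, 0.0403 at a correlation of 0.05 and 0.161 at 0.1, where the call was lost. The same counts held adjusted over the list alone.

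A further 9 lists passed at a preset correlation of 0.01 and were lost at 0.05; of each pair of adjusted p-values given for these, the former is with 0.01 and the latter with 0.05. Cell cycle genes of the G1 to S transition rose in 6 of 31 members (adjusted p = 0.018, then 0.121) and those of G2 and mitosis in 9 of 33 (0.00765, then 0.0772). TGF-beta targets rose in 6 of 19 (0.00953, then 0.0656), matrix genes in 4 of 16 (0.0167, then 0.0772), and epithelial and mesenchymal genes rose in 7 of 21 and fell in 1 (0.0166, then 0.0797). Immediate early genes fell in 4 of 21 (0.00737, then 0.0608), endoplasmic reticulum stress genes in 5 of 22 (0.0296, then 0.125) and replication histones in 2 of 9 (0.0294, then 0.0772). Genes of NF-kappaB and inflammation fell in 6 of 17 members and rose in 4 (0.0449, then 0.127). The cyclin gene CCNE1 stood at 0.41, CDC25A at 0.33 and the mitotic genes PTTG1, AURKA and KIF20A at 0.44, 0.26 and 0.28 in the authors' deposited table. SMAD6, which inhibits TGF-beta family signals, stood at 0.84, TGFBI at 0.66, ID2 at 0.65, and the fibrillins FBN2 and FBN1 at 0.77 and 0.48 in the authors' deposited table. KRT8 and ITGB1 stood at 0.31 and 0.23 in the authors' deposited table. The transcription factors KLF6, NR4A2 and NR4A3 stood at -0.51, -0.78 and -0.62, and JUND, with 69.7% GC, was 1.99-fold lower in the authors' deposited table. The chaperone DNAJB9 stood at -0.74, HERPUD1 at -0.40, the histones H2BC12 and H4C14 at -0.48 and -0.41, and BIRC3, RELB and CCL5 at -0.76, -0.80 and -1.06 in the authors' deposited table. Counts adjusted over the list alone were 7 higher for G1 to S, 12 higher for G2 and mitosis, 8 lower for immediate early genes, 3 lower for histones, and 8 higher and 2 lower for epithelial and mesenchymal genes. They were unchanged for the other 4 lists.

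Insulin, PI3K and mTOR signalling genes fell in 5 of 26 members and rose in 1, and the set did not pass (adjusted p = 0.291). The insulin receptor substrates IRS1 and IRS2 stood at -0.71 and -0.44, PIK3CA at -0.41 and AKT1 at 0.23 in the authors' deposited table, each past the gene test, a call that PIK3CA lost once the length and GC trend was removed, which left it at -0.24. Genes of microRNA processing had 1 of 21 members higher, YBX1 at 0.26 in the authors' deposited table (set adjusted p = 0.251), a call also lost with that trend removed, at a similar value of 0.23. Genes of exosome and endosome function had 2 of 29 higher and 1 lower (adjusted p = 0.277), and ribosomal protein genes 2 of 57 higher (adjusted p = 0.163). Hypoxia targets had 3 of 21 higher and 1 lower (adjusted p = 0.289), p53 targets 2 of 29 higher and 3 lower (0.291), and YAP targets 4 of 22 higher and 2 lower (0.123). Invasion proteases had 4 of 17 higher and 2 lower (adjusted p = 0.229), integrins 4 of 19 higher and 3 lower (0.834), and angiogenic factors 1 of 13 higher and 3 lower (0.851). Antioxidant genes had 3 of 27 higher and 4 lower (adjusted p = 0.799), stromal markers 1 of 8 in each direction (0.637), and senescence genes 3 of 20 higher and 2 lower (0.405). Single members differed in direction: ALCAM, ITGB8 and ITGA2 stood at -0.72, -0.73 and -0.42 beside ITGA5 in the integrin list, and NT5E at -0.97 beside AXL at 0.58 among YAP targets of the authors' deposited table. The metallothionein MT1X, 1 of a family of similar genes, stood at 1.14, NDRG1 at 0.46, EDN1 at 0.54, SERPINE2 at -1.06 and CDKN1A at -0.39 in the authors' deposited table. Adjusted over the list alone, the counts of higher and lower members were 5 and 3 for proteases, 5 and 3 for integrins, 6 and 2 for YAP targets, 4 and 5 for antioxidant genes, and 3 and 4 for senescence genes. They were 2 and 0 for the nuclear respiratory chain, 1 and 0 for ribosomal proteins, 0 and 0 for microRNA processing and 2 and 4 for p53 targets, and unchanged for the remaining lists of this group. The median, the mean and the direction of the set test differed in sign for the nuclear respiratory chain, mitochondrially encoded, integrin, angiogenic, antioxidant, stromal and senescence lists. In all, 18 of 36 lists passed, 8 higher and 10 lower.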

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

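The thresholds of an adjusted p under 0.01, of a log2 fold of at least 1 and the removal of mitochondrially encoded genes were planned; all other settings here were chosen after the data were seen. At an adjusted p under 0.01, 624 genes were higher and 557 lower. With an absolute log2 fold of at least 1, 28 were higher and 89 lower, and with Bonferroni adjustment 176 and 220, so the higher calls lost more with stricter bounds. These fall because each bound is stricter. Counts stayed within 1.5 times the main ones without mitochondrially encoded genes (1081 and 951), over all genes with a fold other than 1 (819 and 730), for protein-coding genes only (1076 and 892) and with the length and GC trend removed (947 and 893, or 948 and 901 with the fourth degree). The 18 lists past the threshold became 9 at a correlation of 0.05, 7 at 0.1 and 11 with log2 fold changes in place of z, the first 2 because a larger correlation widens the error, while the cause of the last was not tested. Ranks of z gave 12, without the trophoblast, epithelial and mesenchymal, matrix, TGF-beta, endoplasmic reticulum stress and NF-kappaB lists, and Fisher's exact test of the members gave 14, without the endoplasmic reticulum stress, G1 to S, matrix, immediate early and histone lists and with the syncytiotrophoblast markers added. Over all genes with a fold other than 1, 21 lists passed: 17 of the 18, without the histones, and 4 more, the tricarboxylic acid cycle, YAP targets, ribosomal proteins and syncytiotrophoblast markers, all higher. Log2 fold changes lost the lysosome list, both cell cycle lists and the epithelial and mesenchymal, matrix, endoplasmic reticulum stress and NF-kappaB lists. With the trend removed, all 18 list calls were kept in the same direction. Of 51 higher and 18 lower GO terms, 40 and 15 were kept with the trend removed, and 42 and 14 with the fourth degree. Of 13 higher and 7 lower KEGG maps, 11 and 5 were kept, and 12 and 4 with the fourth degree. Of the named genes, 6 lost and 2 gained their call with the trend removed, and 9 lost it over all genes with a fold other than 1. YBX1, BNIP3, SLC2A1 and RRM2B lost it under both, PIK3CA and VEGFB under the first, and CDKN1A, CYC1, H4C14, MANF and RPL9 under the second. No named gene past the threshold changed direction with the trend removed or over all genes with a fold other than 1, and no list past the threshold did in the set tests. The median of the angiogenic list, which did not pass, went from -0.04 to 0.06 with the trend removed. The medians of a few lower GO and KEGG terms near 0 also changed sign, among them cellular response to fatty acid, from -0.03 to 0.09.

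No paired analysis was possible because the deposited table has no values per sample. For the same reason other scalings, filters on low counts or values, other count models, a replicate block, pseudocounts, other units, estimated correlations, rotation tests, leaving out each sample, other splits of the samples and library composition were not run. The depth of each sample is unknown, so which low genes could not be called at this depth cannot be stated.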

Other observations

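The tests of length and GC bias on the sterol and fatty acid list medians, on the interferon-stimulated members that passed and on the glycolysis and heat shock medians, and those of interferon signalling genes and of microRNA sites, were set before their outcomes were seen. All others in this part were chosen after the result was seen. The tests on glycolysis and heat shock genes, on placental carry-over and on the interferon-stimulated members that passed were dropped after results bearing on them were known, 1 of them replaced, and then reinstated as first written.

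Genes of the chaperonin that folds actin and tubulin were higher in 6 of 8 tested members and lower in none, and CCT3, CCT7, CCT5 and TCP1 stood at 0.54, 0.50, 0.41 and 0.42 in the authors' deposited table. A list of actin and contractile genes regulated by SRF had 12 of 22 tested members higher and 1 lower. LIMA1, TAGLN2, CCN1 and ANKRD1 stood at 0.78, 0.64, 0.70 and 1.17 in the authors' deposited table. A list of FOXO targets, genes that rise when insulin and growth factors are low, had 10 of 18 members lower and 1 higher. FBXO32, KLHL24, TXNIP and CDKN1B stood at -1.04, -0.77, -0.46 and -0.51 in the authors' deposited table. Splicing genes U2AF2 and DDX23 stood at 0.44 and 0.43, and the lysosomal hydrolases ASAH1 and NEU1 at -0.59 and -0.48 in the authors' deposited table.

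Median changes varied with the GC content of transcripts, though the trend on length and GC took up only 4.04% of the variance of log2 fold changes. In the lowest of 20 GC bins 8 genes were higher and 91 lower, in the bin from 52.8% to 54.5% GC 99 were higher and 32 lower, and in the highest bin 27 and 48. GC content as the whole source of the higher proteasome genes is not borne out, since their median log2 fold was 0.27 before the trend was removed and 0.274 after it. A GC bias between libraries may account for part of the small changes of other genes: among 47 ribosomal and respiratory chain subunit genes above 50% GC the correlation of log2 fold with GC across genes, which are not independent replicates, was -0.28 (Spearman, permutation p = 0.0572). This met the bound on size and missed that on p, so bias and biology cannot be told apart for the small changes.

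The fall of sterol and fatty acid synthesis genes was weighed against 3 explanations. Length and GC bias is argued against, because the medians stayed at -0.95 for the sterol list and -0.415 for the fatty acid list after the trend was removed. A uniform shift between groups is argued against because the list that fell less lay -0.383 from the median of all tested genes, a gap that scaling leaves as it is, while that median itself, -0.00186, decides nothing because scaling may centre it. Cholesterol loading that activates LXR would raise ABCA1 and ABCG1, which stood at -0.46 and -0.49 in the authors' deposited table, and the median of 8 LXR targets was -0.284 (set adjusted p = 0.00952). That set test was not run at correlations above 0.01. Lower SREBP activity, from lipid carried by exosomes or from a difference in medium, remains a hypothesis that was not tested, and SREBF2 itself stood at -0.35 in the authors' deposited table.

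Trophoblast and placental markers that rose may reflect placental RNA carried in with the exosomes. Of 16 abundant placental transcripts with a row, 6 were tested, and 50% of these 6 were past the threshold and higher (PSG4, PSG5 and TFPI2). The set test gave an adjusted p of 0.115. The share met neither bound set for this test, so carry-over and a response of the cells cannot be told apart. It leaves out the listed transcripts that were not tested. The hormone subunit CGA stood at -0.47 in the authors' deposited table, CSH1 and KISS1 are listed with a fold of exactly 1, and CSH2 stood at -1.32 with a p of 0.62 outside the genes tested.

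For glycolysis and heat shock genes, the lower of the 2 list medians was 0.263 with the length and GC trend removed. Both sets stayed past the threshold, which argues against length and GC bias as their whole source. Ribosomal protein and mitochondrially encoded genes, among the most abundant transcripts, had medians of 0.0811 and -0.0134. Glycolysis and heat shock medians were 0.29 and 0.247 before the trend was removed. This argues against a shift of all abundant transcripts alike. With the trend removed, all 31 tested interferon-stimulated genes had a median of -0.148, and the set stayed past the threshold (larger adjusted p of both trends, 2.00e-09), which argues against length and GC bias as the whole source. The median of -0.786 among the members that had passed decides nothing, since these were chosen by their change, and 10 interferon receptor, kinase and transcription factor genes had a median of -0.0571 (set adjusted p = 0.621). None of the 10 passed the authors' test, and 1 had an unadjusted p under 0.05. STAT1, STAT2 and IRF9 are in both the signalling and the interferon-stimulated lists, so these lists overlap. It was hypothesised that a growth factor or serum difference between the cultures may lower FOXO targets and raise SRF targets, and both lists passed the set test in that direction with an adjusted p of 9.91e-07. Both lists were chosen after single members had been seen to change, so this result decides nothing in favour of the hypothesis. Feedback genes of MAPK signalling and immediate early genes, which growth factors and serum also raise, were lower, opposite to more of either in the co-culture. Their set adjusted p was 1.74e-04 and 0.00737, the latter lost at a correlation of 0.05. The MAPK feedback and immediate early lists were set before the table was seen, unlike the FOXO and SRF lists. Their use for this question was still chosen after their direction was seen. They go against more growth factor or serum in the co-culture while the FOXO and SRF lists go with it, so the hypothesis stays undecided. The labels do not say whether untreated cells received the carrier of the exosomes.

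Transfer of placental microRNAs was tested as a fall of genes with their sites. None of 19 families tested was lower at an adjusted p under 0.05 in the linear model of sites, none had an unadjusted p under 0.05, and the lowest family, that of miR-520 and miR-302, stood at the 11.8th percentile among all 7-base words. Estimated site effects of the 19 families ran from -0.0196 to 0.011 on the log2 scale. The family of miR-126-3p, with sites in 30 genes, was not tested. In simulated data 3 of 5 drawn families were recovered at an effect of -0.05 and 5 of 5 at -0.1. The draws were made from all 20 families, with sites in 30 to 2996 genes, so they set no bound for a single family. A small effect on transcripts, or one on protein alone, stays open. MicroRNAs outside the listed families were not tested.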
